A study of Rattus norvegicus with 8 samples.

How the data were processed

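RNA of 8 libraries of SF2 rat dental epithelial cells was profiled, 1 library for each combination of genotype (AmeloD-overexpressing or Control), plasmid label (pCMV6 or pCMV6.ODAM) and the label N or TGF. Per the labels' protocols, total RNA of integrity number 9.0 or above was made into libraries with the QIAseq UPX 3' Transcriptome kit and an MGI conversion kit and sequenced as 150-base paired ends on a DNBSEQ-G400. Reads were trimmed, aligned with STAR to mRatBN7.2 and counted with featureCounts, per the labels' protocols. Per the submitters' processing notes the versions were Trim Galore 0.6.7, Trimmomatic 0.39, cutadapt 3.7, STAR 2.7.10a, featureCounts 2.0.1 and DESeq2 1.20.0. Whether molecular identifiers were used, the strand setting and the treatment of reads shared between genes are not given in the sources used here.

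The authors deposited a single table of CPM per gene and library, with gene identifiers, symbols, coordinates and Gene Ontology terms. It had 30240 rows, of which 4319 had no symbol and 0 lay on the mitochondrial chromosome, so the list of mitochondrially encoded mRNAs was not analysed here. The deposited CPM summed to 156393 to 175071 per library, that is 15.6% to 17.5% of the library total they were scaled to. The low values were whole multiples of the CPM of 1 read, and all values (100%) came out as whole reads within a tolerance of 0.01. The recovered library totals were 10568146 to 17775226 reads, and 1662973 to 2854134 of these reads lay in the table. The 10 most abundant genes held 19.8% to 22.6% of the reads of a library. A count of 0 was taken to allow up to 3 reads, which is 0.169 to 0.284 CPM per library. Intervals and floors cover counting error only, since reads need not be independent molecules. Correlations of log2 values between libraries were 0.948 to 0.981.

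The main test was limma 3.58.1 in R 4.3.3 on log2(CPM + 1) as deposited, with the eBayes trend, genotype, plasmid and TGF as additive terms over all 8 libraries, two-sided, with Benjamini-Hochberg adjustment over the 6849 genes at 1 CPM or more in at least 4 libraries and a threshold of 0.05. Of these genes 208 had no symbol, and they held at least 98.5% of the table's reads in each library. Because no combination was replicated, the 4 residual degrees of freedom hold the interactions as well as the spread between libraries; the interaction models have 3. A matched pair is 2 libraries that differ in the tested factor alone. The sets of 4 pairs are given as values, since a pair of single libraries has no replicate check. On simulated data with 200 of 6849 genes changed between the genotypes, the limma step recovered 30%, 54%, 100% and 100% of genes changed 1.5-, 2-, 4- and 8-fold, with 4.05% false calls among those made. For a simulated genotype by TGF interaction it recovered 4%, 12%, 90% and 76%. In both simulations the 1.5- and 4-fold changes were rises and the 2- and 8-fold changes were falls. Size and direction of change were thus not separated. The simulated libraries varied independently around their true totals, so the 4.05% does not cover scaling error or dependence between libraries. On simulated lists the list test, camera, called the changed list (adjusted p = 6.31e-47) and 0 of 20 unchanged lists. The simulated genes varied independently, so this does not show how often unchanged lists of correlated genes are called. The comparisons, their main tests, the gene lists, the rule for named genes and the alternatives, except those said to be added later, were fixed before the data were examined.

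There were 22 gene lists with 466 symbols, of which 443 were matched, 2 of them by an older symbol. They cover Hedgehog components and targets, DNA replication, mitosis, enamel matrix, dental epithelial progenitors, epithelial and mesenchymal genes, TGF-beta, BMP, Wnt, Notch, FGF and interferon responses, p53 targets, endoplasmic reticulum stress, cholesterol synthesis, hypoxia and glycolysis, markers of odontoblasts, leukocytes and endothelium, and mitochondrially encoded mRNAs. Several genes stand in more than 1 list, and values of some members are not reported here. The 14 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 14 lists of a comparison. No genotype or plasmid list passed with the estimated correlation, and for TGF only the TGF-beta induced genes did. That setting also rests on the few residual degrees of freedom, so its larger p values do not measure the correlation alone.

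Named genes were, for genotype, the 8 largest rises and 8 largest falls among genes past the test with a mean of at least 10 CPM and the same sign in all 4 pairs, and for TGF and plasmid the 5 largest each way by that rule; for the interactions up to 3 each way. Genes without a proper symbol were skipped. Ascl5 and Odam were always named, as were up to 4 members past the test per list, or the 2 with the smallest p where none passed. Gene Ontology terms in the deposited table with 10 to 300 genes (1282 terms, 5854 tested genes with a term as background) were tested with a one-sided hypergeometric test and Benjamini-Hochberg adjustment. That step called a term in 0 of 20 random gene sets and found a planted term (hypergeometric adjusted p = 2.75e-05). Random sets do not cover genes of a term that vary together. Neighbouring genes were looked up in the RefSeq annotation of GRCr8, another assembly than the files', for names and order only.

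The alternatives were pseudocounts of 0.5 and 5, no filter or a mean of at least 10 CPM, libraries shifted to the same median, TMM scaling, robust eBayes, edgeR 4.0.16 quasi-likelihood tests and DESeq2 1.42.0 on the recovered reads, leaving out each library, a 4-level covariate, genotype alone, N or TGF libraries alone and an estimated correlation for the lists. Reads thinned to the smallest library total were added after the data were seen. The fits of N or TGF libraries alone use 4 libraries each, so their p values rest on few residual degrees of freedom. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.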

Results

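Messenger RNA was measured in SF2 cells, an epithelial line derived from the cervical loop of the rat mandibular incisor, the tissue at the base of the tooth that supplies the enamel-forming ameloblasts. The cells were labelled as overexpressing AmeloD, a basic helix-loop-helix transcription factor of the dental epithelium encoded by Ascl5, or as Control. Each genotype was combined with either of a pair of plasmid labels, pCMV6 or pCMV6.ODAM (Odam encodes odontogenic ameloblast-associated protein), and with either of the labels N and TGF, which the labels do not spell out. The 8 combinations had 1 library each, so that each genotype, plasmid and TGF label was carried by 4 libraries and no combination had a replicate. The 3'-end libraries totalled 10568146, 13484330, 13668736 and 10823522 reads for AmeloD and 15977656, 14766931, 15388542 and 17775226 for Control (each in the order pCMV6 N, pCMV6.ODAM N, pCMV6.ODAM TGF, pCMV6 TGF), so the AmeloD libraries were the shallower. Of these, 1662973 to 2854134 reads per library fell on rows of the gene table. Between 12453 and 13152 genes had at least 1 read, and 6849 genes were tested. Values are CPM as mean ± SD over the 4 libraries of a group, which includes the other factors' differences. Changes are log2 fold changes ± SE on the log2(CPM + 1) scale, which understates changes of low genes. Adjusted p values are from limma with Benjamini-Hochberg adjustment unless another tool is named. The first principal component held 40.6% of the variance and separated the genotypes, and the next held 16.7% and separated the TGF libraries from the N libraries.

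**Figure D1:**
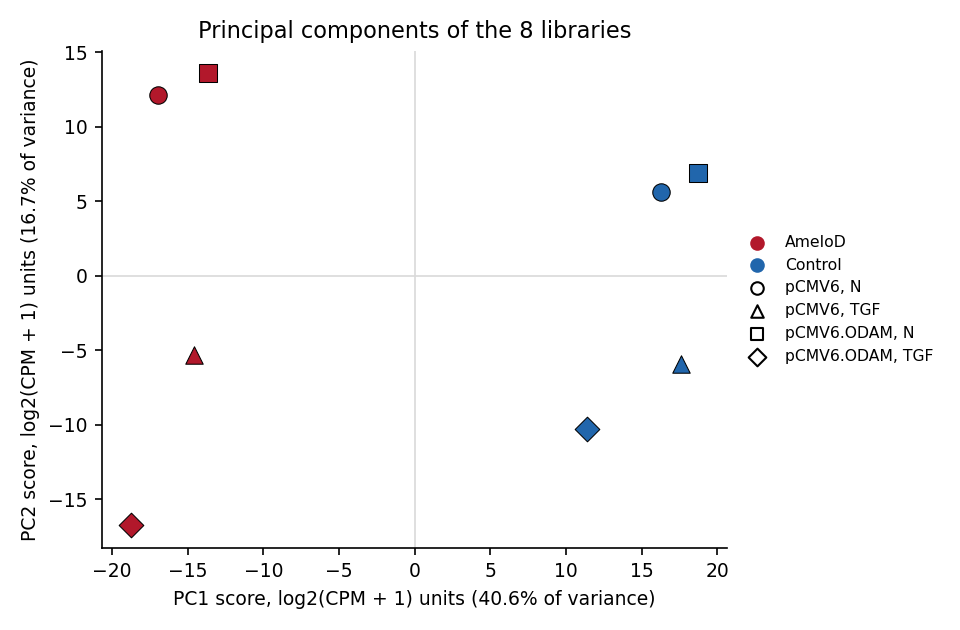
First and second principal components of log2(CPM + 1) over the 6849 tested genes; each point is 1 of the 8 libraries, and the axes give the percent of variance. The first component (40.6%) parts the AmeloD from the Control libraries and the second (16.7%) parts the TGF from the N libraries.

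The genes named by the labels were read first. Ascl5 (ENSRNOG00000033391, chromosome 13, 47492026 to 47492592 in mRatBN7.2) had 0 reads in all 8 libraries. Its model in the table is a single coding stretch without untranslated ends, and a 3' library need not count a construct without the native 3' end, so this value neither checks nor contradicts the AmeloD labels. By the floor of 3 reads, 0 reads allowed up to 0.169 to 0.284 CPM per library, a bound that covers counting error only. Odam (ENSRNOG00000023372, chromosome 14, 20193302 to 20202517) had 31 reads in the 4 pCMV6.ODAM libraries and 1 read in the 4 pCMV6 libraries (two-sided exact binomial p = 1.79e-08, a test of these libraries' reads). Within the pCMV6.ODAM libraries, Control had 27 Odam reads (10 with N, 17 with TGF) and AmeloD had 4 (1 and 3). The AmeloD to Control ratio of Odam reads, scaled to the library totals, was 0.165, with an exact 95% interval of 0.0418 to 0.472.

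The comparison of AmeloD with Control libraries addressed which genes differ in cells overexpressing AmeloD. Among genes with a mean of at least 10 CPM, the 8 largest rises included Cnfn, Krtdap, Sprr1a and Lce3d, genes of the cornified epithelium. Mal, a lipid-raft protein of epithelial apical transport, was at 19.5 ± 6.07 CPM in AmeloD and 1.36 ± 0.534 in Control, an 8.54-fold difference on the CPM + 1 scale. Slpi, a secreted protease inhibitor, was at 21.6 ± 3.40 against 1.94 ± 0.686 CPM. The largest falls among such genes were of Prl8a7, a member of the placental prolactin family, which had 3 reads in all AmeloD libraries and 2098 in all Control libraries, and of the insulin-like growth factor binding protein gene Igfbp5. In all, 946 genes passed the test, 621 higher and 325 lower in AmeloD (65.6% higher), and 112 of the rises and 38 of the falls exceeded 1 log2 unit.

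Among the largest rises, Mal (ENSRNOG00000015445, chromosome 3, 114864378 to 114888136) rose by 3.09 ± 0.16 (adjusted p = 3.94e-13) and Slpi by 2.97 ± 0.17 (adjusted p = 1.45e-12). Cnfn, encoding cornifelin of the cornified envelope, rose by 2.50 ± 0.13, from 72.9 ± 25.2 to 404 ± 39.5 CPM. Krtdap, a keratinocyte differentiation-associated gene (ENSRNOG00000062262, chromosome 1, 86038437 to 86041455), rose by 2.48 ± 0.11, from 16.1 ± 4.82 to 93.5 ± 22.4 CPM (adjusted p = 4.74e-14). The cornified envelope precursors Sprr1a and Lce3d rose by 2.27 ± 0.12 and 1.77 ± 0.10, the mucosal keratin Krt13 by 2.09 ± 0.14 and the small heat shock protein gene Cryab by 1.64 ± 0.11. The rule for naming these 8 genes required a rise in all 4 matched pairs of libraries, so that agreement is no further support. Sprr, Lce and keratin genes have close paralogs, and how shared reads were counted is not given in the sources used here.

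Among the largest falls, Prl8a7 (ENSRNOG00000016933, chromosome 17, 37558883 to 37564718) changed by -4.63 ± 0.26 (adjusted p = 1.13e-12). Its AmeloD to Control ratio of reads, scaled to the library totals, was 0.00188, with an exact 95% interval of 0.000388 to 0.00551, and reads shared with its near relatives cannot be excluded. Igfbp5 was at 3.84 ± 3.20 CPM in AmeloD and 33.0 ± 24.5 in Control (-2.75 ± 0.15, adjusted p = 5.97e-13). Mt1, encoding a metal-binding metallothionein, was at 14.2 ± 4.32 and 82.7 ± 15.9 CPM (-2.49 ± 0.13). Ldha, encoding lactate dehydrogenase A, was at 73.8 ± 4.47 and 169 ± 21.3 CPM (-1.18 ± 0.10, adjusted p = 4.36e-09). Fam162a, Serpine2, Ndrg1 and Col3a1 fell by 1.39 ± 0.15, 1.26 ± 0.15, 1.22 ± 0.14 and 1.11 ± 0.13. A fall in all 4 matched pairs was likewise a condition for naming these 8 genes.

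**Figure D2:**
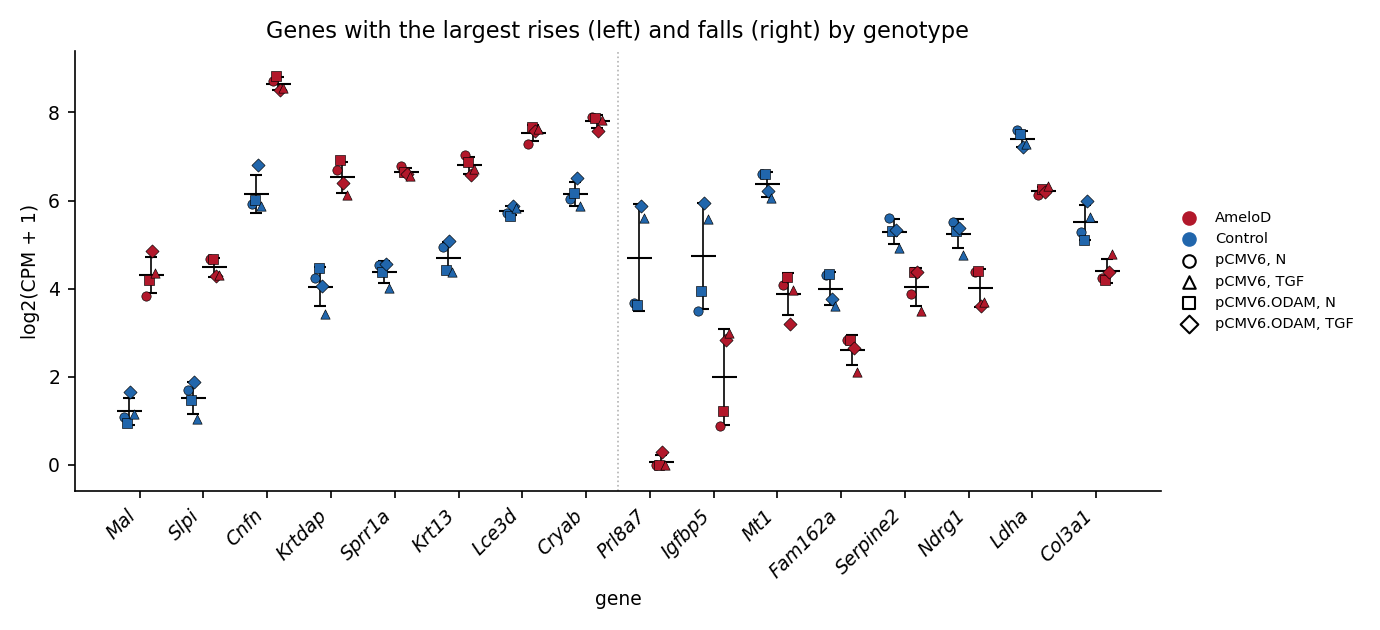
Log2(CPM + 1) of the 16 genes with the largest genotype rises and falls; points are libraries, coloured by genotype, and bars give the mean ± SD of the 4 libraries of a genotype. Mal lies at 19.5 CPM in AmeloD against 1.36 in Control on average, and Prl8a7 at 0.0549 against 32.2.

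The title of the series names Sonic hedgehog signalling. Shh and Gli2 had 0 reads in the 8 libraries and Hhip had 1. Gli1 had 9 reads (7 in AmeloD), Gli3 7 (6 in AmeloD) and Ptch1 27 (9 in AmeloD, 18 in Control), and none of these genes reached the level needed for a test. Of the 27 Hedgehog pathway components listed, 6 were tested: 2 rose, 0 fell and 4 did not pass, and 2 rose when adjusted over the list alone. Smo, the signal transducer of the pathway, rose by 1.12 ± 0.18 (adjusted p = 9.24e-05), from 0.371 ± 0.129 to 1.98 ± 0.360 CPM, on 24 reads in Control and 95 in AmeloD. Prkaca, the catalytic subunit of protein kinase A, rose by 0.51 ± 0.16 (adjusted p = 0.0361). As a list the components did not stand apart from other genes (median 0.31, camera adjusted p = 0.0719). The list pools components whether they promote or restrain the pathway, so its counts and median give no direction of signalling. Of 4 tested Hedgehog target genes, 2 rose, 0 fell and 2 did not pass, with 2 rises adjusted over the list alone. These were the D-type cyclins Ccnd2 (2.93 ± 1.14 against 0.156 ± 0.0624 CPM, a rise of 1.72 ± 0.19, adjusted p = 3.69e-07) and Ccnd1 (34.5 ± 9.58 against 22.7 ± 5.63 CPM, 0.57 ± 0.13, adjusted p = 0.00342).

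The title also names proliferation. Of 27 tested DNA replication genes 7 fell, 1 rose and 19 did not pass (8 fell and 1 rose adjusted over the list alone), and 22 of the 27 lay below 0. The falls included the chromatin remodeller Hells (-0.66 ± 0.11, adjusted p = 0.000139), the ribonucleotide reductase subunit Rrm2 (-0.91 ± 0.18, adjusted p = 0.00107) and the replicative helicase subunit Mcm3 (-0.78 ± 0.19, adjusted p = 0.00683). The rise was Ccne1, the G1/S cyclin E1, by 0.75 ± 0.18 (adjusted p = 0.00611). The list lay below other genes (median -0.36, camera adjusted p = 4.29e-05; adjusted p = 0.206 with an estimated correlation). Of 26 tested mitosis genes 5 fell, 0 rose and 21 did not pass (11 fell adjusted over the list alone), and 23 of the 26 lay below 0. Mki67, the proliferation marker Ki-67, was at 7.82 ± 2.30 CPM in AmeloD and 13.5 ± 2.06 in Control (-0.75 ± 0.15, adjusted p = 0.00111). The contractile ring gene Anln fell by 0.70 ± 0.15, the mitotic cyclin Ccnb1 by 0.50 ± 0.13 and the chromatin protein gene Hmgb2 by 0.43 ± 0.12. The mitosis list lay below other genes too (median -0.35, camera adjusted p = 5.22e-06; adjusted p = 0.206 with an estimated correlation).

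For differentiation, 5 of 20 listed enamel matrix and ameloblast genes were tested, of which 1 rose, 0 fell and 4 did not pass, with 1 rise adjusted over the list alone. Tuft1, encoding tuftelin of the enamel organ, rose by 0.61 ± 0.19 (adjusted p = 0.0285), from 1.03 ± 0.381 to 2.09 ± 0.490 CPM. The list had a median of 0.30 and a camera adjusted p of 0.140. Amelx, Ambn, Enam, Amtn, Klk4, Mmp20 and Dspp, which encode enamel or dentin matrix proteins and enamel proteases, had 0 reads in all 8 libraries. Of 13 tested dental epithelial progenitor and signalling genes 6 rose, 1 fell and 6 did not pass, with the same counts adjusted over the list alone. Krt17 rose by 0.65 ± 0.08, from 331 ± 36.7 to 517 ± 21.1 CPM (adjusted p = 4.86e-06), the ligand gene Wnt7b by 1.17 ± 0.17, the receptor gene Notch1 by 0.80 ± 0.14 and the basal keratin Krt5 by 0.37 ± 0.09. The list lay above other genes (median 0.35, camera adjusted p = 0.00846; adjusted p = 0.274 with an estimated correlation).

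Of 29 tested epithelial junction and keratin genes 12 rose, 1 fell and 16 did not pass (16 rose and 2 fell adjusted over the list alone). The tight junction gene Cldn3 rose by 1.96 ± 0.19 (adjusted p = 5.52e-08), the desmosomal cadherin Dsc2 by 1.21 ± 0.19 and Krt7 by 0.92 ± 0.11, from 98.7 ± 18.8 to 195 ± 74.7 CPM. Krt8, a keratin of simple epithelia, fell by 1.06 ± 0.16 (adjusted p = 4.55e-05). The epithelial list lay above other genes (median 0.37, camera adjusted p = 0.000148; adjusted p = 0.206 with an estimated correlation). Of 11 tested mesenchymal and fibroblast markers 5 fell, 1 rose and 5 did not pass (6 fell and 1 rose adjusted over the list alone). The fibrillar collagens Col3a1 and Col5a2 fell by 1.11 ± 0.13 and 0.83 ± 0.15. Fibronectin, Fn1, fell by 0.59 ± 0.14 (adjusted p = 0.00392) but was higher in AmeloD in 1 of the 4 pairs, with -0.89 in the N libraries alone and -0.29 (adjusted p = 0.402) in the TGF libraries alone, and the matricellular gene Sparc rose by 0.59 ± 0.13. The mesenchymal list lay below other genes (median -0.22, camera adjusted p = 0.00722; adjusted p = 0.257 with an estimated correlation).

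Of 10 tested hypoxia and glycolysis genes 6 fell, 1 rose and 3 did not pass, with the same counts adjusted over the list alone. Besides Ldha and Ndrg1, the phosphoglycerate kinase gene Pgk1 fell by 0.71 ± 0.10 (adjusted p = 2.20e-05), from 74.2 ± 15.6 to 45.1 ± 10.03 CPM. The oxygen-sensing prolyl hydroxylase gene Egln3 rose by 1.16 ± 0.17 (adjusted p = 3.64e-05). The list had a median of -0.57 and a camera adjusted p of 5.49e-06, with adjusted p = 0.179 with an estimated correlation. Of 17 tested endoplasmic reticulum stress genes 8 rose, 0 fell and 9 did not pass (9 rose adjusted over the list alone). The chaperones and their partners Hspa5 (59.0 ± 3.60 to 116 ± 30.03 CPM, 0.92 ± 0.13), Sdf2l1 (1.09 ± 0.14), Hsp90b1 (0.89 ± 0.13) and Calr (0.59 ± 0.13) were among the rises. Their list had a median of 0.48 and a camera adjusted p of 0.00323, with adjusted p = 0.307 with an estimated correlation.

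In the FGF and ERK response list, 3 of 8 tested genes fell, 0 rose and 5 did not pass, with 3 falls adjusted over the list alone. The transcription factor genes Fosl1, Egr1 and Etv1 fell by 1.23 ± 0.19, 0.92 ± 0.18 and 0.74 ± 0.18, and the list had a median of -0.11 (camera adjusted p = 0.00976; adjusted p = 0.206 with an estimated correlation). Of 12 tested TGF-beta induced genes only Ccn2, a matricellular growth factor, rose (1.54 ± 0.15, adjusted p = 5.19e-08; also adjusted over the list alone), 0 fell and 11 did not pass, and the list's camera adjusted p was 0.233. Of 13 tested p53 targets 3 rose, the death receptor gene Fas by 1.10 ± 0.17, the BH3-only gene Pmaip1 by 0.97 ± 0.21 and Gadd45a by 0.47 ± 0.16 (adjusted p = 0.0476), 0 fell and 10 did not pass (4 rose adjusted over the list alone, camera adjusted p = 0.118). Of 7 tested interferon response genes Irf7 rose by 0.78 ± 0.21, Usp18 fell by 0.62 ± 0.18 and 5 did not pass (2 rose and 1 fell adjusted over the list alone, camera adjusted p = 0.559). Of 12 tested cholesterol synthesis genes Nsdhl rose by 0.71 ± 0.20, Cyp51 fell by 0.55 ± 0.17 (higher in 1 of the 4 pairs; -0.08 in the N libraries alone, adjusted p = 0.876, and -1.01 in the TGF libraries alone) and 10 did not pass, with 1 rise and 1 fall adjusted over the list alone. The cholesterol list had a positive median (0.11) and mean (0.06) while camera placed it downward (adjusted p = 0.975).

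The lists with under 5 tested members gave counts only. Of 3 tested BMP targets and Id genes Id4 fell by 0.60 ± 0.18 and 2 did not pass, with 1 fall adjusted over the list alone. Of 4 tested Notch targets Notch1 rose and 3 did not pass (1 rose and 1 fell adjusted over the list alone). The only tested Wnt target, Cd44, had a change of -0.07 ± 0.15 (adjusted p = 0.821). Among markers of other cell types, the odontoblast and bone list had 1 tested gene, Spp1, at 0.44 ± 0.19 (adjusted p = 0.121, past the test adjusted over the list alone), and the endothelial list had Egfl7 at -0.12 ± 0.19 (adjusted p = 0.762). The leukocyte list had 1 tested gene, the lysosomal gene Cd68, which rose by 0.95 ± 0.18 (adjusted p = 0.000792; also adjusted over the list alone), on 156 reads in AmeloD and 77 in Control. The other leukocyte markers had 11 reads or fewer each in the 8 libraries together, 11 for Fcer1g and 1 for Ptprc.

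The split of the genotype calls into higher and lower depended on the scaling: TMM scaling gave 532 higher and 474 lower (52.9% higher), a shift of the libraries to the same median 490 and 510, edgeR on the recovered reads 519 and 438, and DESeq2 414 and 363. The genes named here kept their direction in each of these, and leaving out 1 library ended the call of 11 of the 59 named genes in at least 1 case (highest adjusted p = 0.256), namely Prkaca in 7 of 8 cases, Id4 and Gadd45a in 6, Tuft1 in 5, Cyp51 in 4, Hmgb2 in 3, Usp18, Irf7, Nsdhl and Krt5 in 2 and Mcm3 in 1. The calls also ended with TMM scaling for Prkaca (adjusted p = 0.0508) and Gadd45a (adjusted p = 0.0620), with the same median for both (0.0610 and 0.0721), with edgeR for Gadd45a (edgeR adjusted p = 0.0514), and with DESeq2 for Prkaca (DESeq2 adjusted p = 0.112), Gadd45a (0.0922), Tuft1 (0.110), Id4 (0.0582) and Nsdhl (0.0595).

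**Figure D3:**
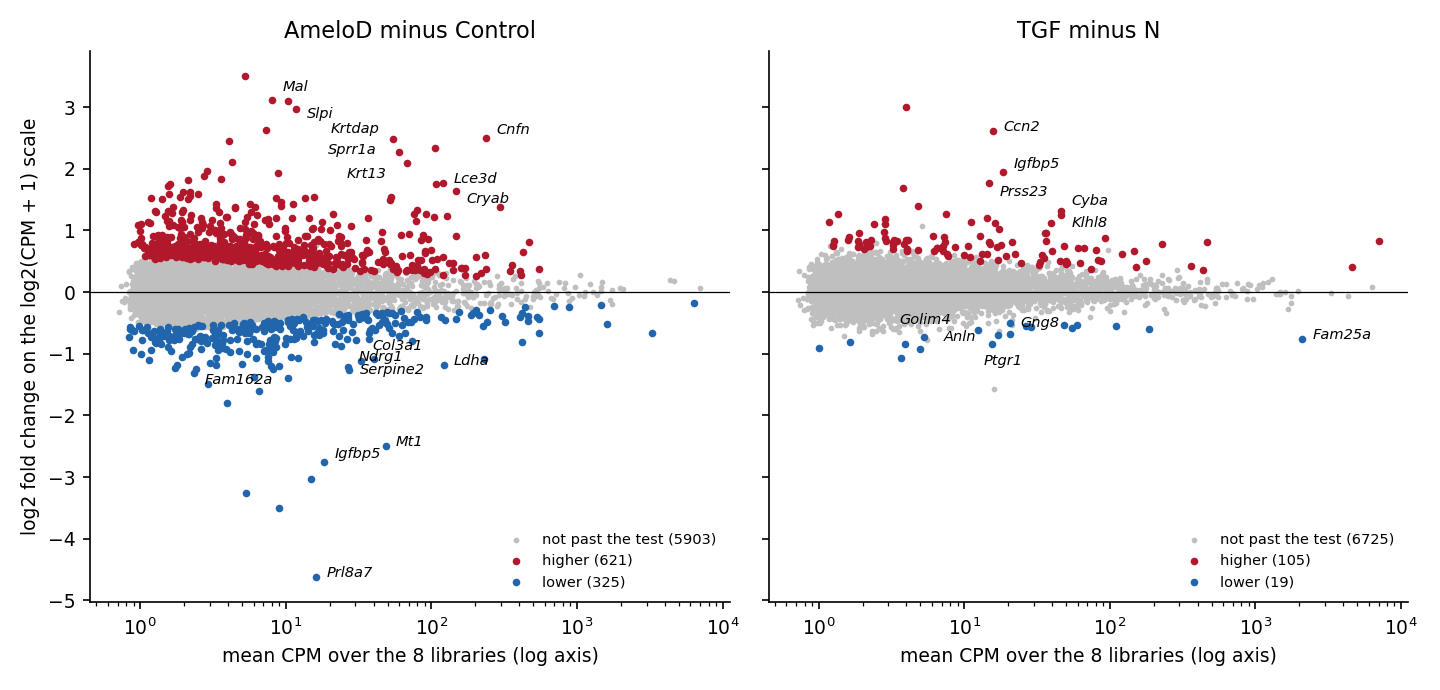
Log2 fold change on the log2(CPM + 1) scale against mean CPM over the 8 libraries (log axis) of the 6849 tested genes for AmeloD minus Control and for TGF minus N; coloured points passed the test at an adjusted p under 0.05. The genotype panel holds 946 such genes, 621 of them higher, and the TGF panel 124, 105 of them higher.

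The comparison of TGF with N libraries addressed the response to the condition labelled TGF. Pmepa1 and Ccn2, known to be induced by transforming growth factor beta, were among the genes that rose most. Pmepa1, a feedback inhibitor of TGF-beta signalling (ENSRNOG00000050404, chromosome 3, 162012751 to 162060454), was at 7.81 ± 1.65 CPM in TGF and 0.0837 ± 0.0619 in N libraries. Ccn2 (ENSRNOG00000015036, chromosome 1, 20802199 to 20805734) was at 27.7 ± 17.4 against 3.71 ± 3.01 CPM. In all, 124 genes passed the test, 105 higher and 19 lower with TGF (84.7% higher), with 19 rises and 1 fall beyond 1 log2 unit.

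The largest rises by the fixed rule were Ccn2 (2.62 ± 0.15, adjusted p = 1.96e-11), Igfbp5 (1.95 ± 0.15, adjusted p = 3.14e-09; 30.1 ± 27.7 against 6.72 ± 6.72 CPM), the serine protease gene Prss23 (1.76 ± 0.15), the NADPH oxidase subunit gene Cyba (1.32 ± 0.11; 66.8 ± 17.8 against 25.8 ± 3.63 CPM) and Klhl8 (1.26 ± 0.11). The largest falls were Ptgr1, a prostaglandin reductase gene (-0.84 ± 0.14, adjusted p = 0.000712), Fam25a (-0.76 ± 0.08, adjusted p = 5.59e-07), Anln (-0.69 ± 0.15), Gng8 (-0.67 ± 0.14) and Golim4 (-0.62 ± 0.14). The rule required each of these 10 genes to move the same way in all 4 pairs of libraries.

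Of 12 tested TGF-beta induced genes 6 rose, 0 fell and 6 did not pass (7 rose adjusted over the list alone). Pmepa1 rose by 3.01 ± 0.19 (adjusted p = 6.30e-11), the clock-linked repressor gene Bhlhe40 by 1.18 ± 0.19 and the integrin subunit gene Itgb6, which also counts among the enamel genes, by 0.76 ± 0.18 (adjusted p = 0.0234). The list's median was 0.56 and its camera adjusted p 2.56e-10, and it was the only list of any comparison whose call held with an estimated correlation (adjusted p = 0.0293). Of 11 tested mesenchymal markers 4 rose, 0 fell and 7 did not pass, with the same counts adjusted over the list alone. Fn1 rose by 1.12 ± 0.14 (adjusted p = 9.41e-06), from 25.2 ± 9.44 to 53.5 ± 9.48 CPM, Sparc by 0.60 ± 0.13, Col5a2 by 0.59 ± 0.15 and Col3a1 by 0.49 ± 0.13 (adjusted p = 0.0401). The mesenchymal list had a camera adjusted p of 0.000434 (adjusted p = 0.227 with an estimated correlation). Of 29 tested epithelial genes 4 rose, 0 fell and 25 did not pass (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0360, adjusted p = 0.455 with an estimated correlation). Of these, Lama3 and Lamb3, which encode laminin chains of the basement membrane, rose by 1.27 ± 0.16 and 0.83 ± 0.11, and Krt7 rose by 0.66 ± 0.11.

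Mitosis genes lay lower with TGF: of 26 tested, Anln fell, 0 rose and 25 did not pass (7 fell adjusted over the list alone), 22 of the 26 lay below 0, and the median was -0.37 (camera adjusted p = 8.96e-10; adjusted p = 0.194 with an estimated correlation). Of 27 tested DNA replication genes 0 passed, over all genes or adjusted over the list alone, while their list had a median of -0.11 and a camera adjusted p of 0.0183 (adjusted p = 0.455 with an estimated correlation). Nasp and Rrm2 had the smallest p of that list, at -0.60 ± 0.22 (adjusted p = 0.217) and -0.38 ± 0.18 (adjusted p = 0.404). Of 4 tested Hedgehog targets Ccnd1 fell by 0.57 ± 0.13 (adjusted p = 0.0174; also adjusted over the list alone) and 3 did not pass. Of 6 tested Hedgehog components 0 passed, also adjusted over the list alone, with Csnk1a1 at -0.24 ± 0.14 and Prkaca at 0.24 ± 0.16 (camera adjusted p = 0.681). Of 10 tested hypoxia and glycolysis genes Pgk1 fell by 0.53 ± 0.10 and Ndrg1 by 0.55 ± 0.14 (higher in 1 of the 4 pairs), 0 rose and 8 did not pass (the same adjusted over the list alone; camera adjusted p = 0.00227, adjusted p = 0.194 with an estimated correlation).

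Of 5 tested enamel genes Itgb6 rose and 4 did not pass (2 rose adjusted over the list alone; camera adjusted p = 0.798, with a median of -0.06 against a mean of 0.15). Of 13 tested dental progenitor genes the activin antagonist gene Fst rose by 0.68 ± 0.10, from 61.4 ± 10.7 to 98.6 ± 14.2 CPM, and 12 did not pass (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.855). Of 13 tested p53 targets Fas rose by 0.92 ± 0.17 and 12 did not pass (2 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.855). The inhibitor of differentiation genes Id1 and Id3, of 3 tested BMP targets and Id genes, had changes of -0.60 ± 0.18 (adjusted p = 0.0916) and -0.51 ± 0.17 (adjusted p = 0.154); 0 members passed over all genes, and 1 rose and 2 fell adjusted over the list alone. No member passed among 8 FGF and ERK response genes (2 rose adjusted over the list alone; camera adjusted p = 0.201; Phlda1 at 0.49 ± 0.15 and Dusp6 at 0.45 ± 0.16) or among 4 Notch targets (1 fell adjusted over the list alone; Notch1 at -0.41 ± 0.14 and Hes1 at 0.27 ± 0.13). No member passed, over all genes or over the list alone, among 7 interferon, 17 endoplasmic reticulum stress and 12 cholesterol genes (camera adjusted p = 0.855 for each). For the last of these 3 lists and the stress list, median and mean were above 0 while camera pointed down. Cd44 had a change of 0.06 ± 0.15, Spp1 of 0.08 ± 0.19, Cd68 of 0.20 ± 0.18 and Egfl7 of 0.37 ± 0.19, and none passed.

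The TGF count was 71 without the AmeloD pCMV6.ODAM N library and 76 without the Control pCMV6.ODAM N library, and TMM scaling gave 86 higher and 29 lower (74.8% higher), a shift to the same median 83 and 28, edgeR 79 and 26, and DESeq2 77 and 32. Leaving out 1 library ended the call of 9 of the 26 named genes in at least 1 case (highest adjusted p = 0.212), namely Col5a2 in 7 of 8 cases, Itgb6, Col3a1 and Ndrg1 in 6, Golim4 and Ccnd1 in 4, and Anln, Gng8 and Sparc in 3. The call of Col3a1 ended with TMM scaling (adjusted p = 0.0654), the same median (0.0626) and edgeR (edgeR adjusted p = 0.0629), Id1 passed with TMM scaling (-0.64, adjusted p = 0.0473) and the same median (-0.65, adjusted p = 0.0473), and with DESeq2 Itgb6 (DESeq2 adjusted p = 0.103) and Col5a2 (0.0775) did not pass.

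**Figure D4:**
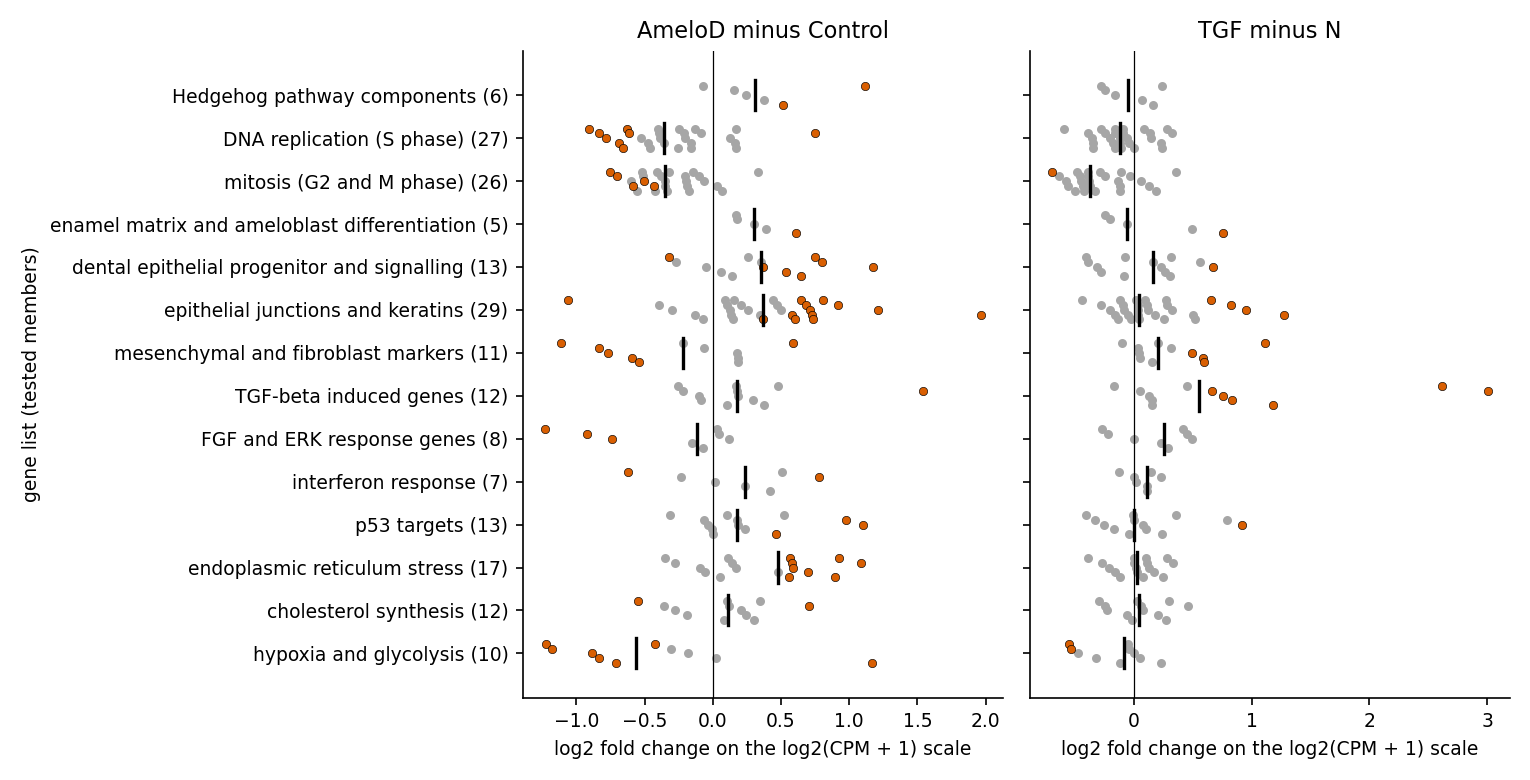
Log2 fold changes of the tested members of the gene lists for AmeloD minus Control and for TGF minus N; each point is a gene, orange points passed the test at an adjusted p under 0.05 and black bars are list medians. The mitosis list has medians of -0.35 and -0.37, and the TGF-beta induced genes have medians of 0.17 and 0.56.

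The comparison of pCMV6.ODAM with pCMV6 libraries addressed the effect of the ODAM plasmid. Odam itself had only 31 reads in the pCMV6.ODAM libraries, 4 of them in AmeloD, so how strongly the plasmid was expressed is not known. In the simulated genotype comparison, limma recovered 30% of genes changed 1.5-fold and 54% of those changed 2-fold. Small plasmid effects could therefore be missed. No gene passed with limma (0 of 6849; 454 at an unadjusted p under 0.05; smallest adjusted p = 0.218) or with edgeR (0), and DESeq2 called 1. That gene was Med27, a subunit of the Mediator complex, chosen after its values were seen, with a DESeq2 log2 fold change of -0.86 ± 0.19 (DESeq2 adjusted p = 0.0226) and a limma value of -0.80 (adjusted p = 0.218). In each of the 21 lists with a tested member 0 members passed, over all genes or adjusted over the list alone. Among the 14 lists with a set test, the mitosis list lay lower with pCMV6.ODAM (median -0.13, 21 of 26 members below 0, camera adjusted p = 0.00363; adjusted p = 0.919 with an estimated correlation). Mki67 and Hmmr, at -0.33 and -0.34, did not pass (adjusted p = 0.724 and 0.759). The other 13 lists had camera adjusted p values of 0.429 to 0.972. With only genes of a mean of at least 10 CPM tested, the mitosis list did not pass (adjusted p = 0.143), while the epithelial list (adjusted p = 0.000896) and the p53 list (adjusted p = 0.0296) did. Without the Control pCMV6.ODAM TGF library the plasmid count was 2. The mitosis list did not pass without the AmeloD pCMV6.ODAM TGF library (adjusted p = 0.195) or without the AmeloD pCMV6 TGF library (adjusted p = 0.317).

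The interaction of genotype and TGF addressed whether the AmeloD and Control cells differed in their response to TGF. On simulated data the interaction step found 4% of 1.5-fold rises, 12% of 2-fold falls, 90% of 4-fold rises and 76% of 8-fold falls. Small differences in response were thus mostly not detectable. Prl8a7 was the only gene past the test with limma (282 genes at an unadjusted p under 0.05), with an interaction of -1.95 ± 0.35 (adjusted p = 0.0185). In Control it was at 11.8 and 11.3 CPM in the N libraries and 47.7 and 58.2 CPM in the TGF libraries. In AmeloD it was at 0, 0 and 0 CPM in 3 libraries and 0.219 CPM, 3 reads, in the pCMV6.ODAM TGF library. On the recovered reads its interaction was 1.68 with edgeR (adjusted p = 1) and 0.79 with DESeq2 (adjusted p = 0.9997), and both tools called 0 genes. The call ended without each of the 4 Control libraries in turn (highest adjusted p = 0.999), and the count was 6 without the AmeloD pCMV6 N library, 7 without the AmeloD pCMV6 TGF library and 2 without the Control pCMV6 TGF library. For the interaction of genotype and plasmid, limma called 0 genes (308 at an unadjusted p under 0.05; smallest adjusted p = 0.727), edgeR 0 and DESeq2 0. The limma count was 2 without the AmeloD pCMV6.ODAM N library and 2 without the AmeloD pCMV6.ODAM TGF library.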

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

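The tests of depth, of other differences between the cell populations, of the scaling, of Prl8a7 and of neighbouring genes were chosen after the results were seen, and the tests on other splits of the libraries before.

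Prl8a7 stood out because the interaction test gave its TGF effect as different between AmeloD and Control cells, at -1.95 on the log2(CPM + 1) scale. The Control libraries had 1742 reads with TGF and 356 with N, a ratio of 4.54 when scaled to the library totals. The AmeloD libraries had 3 reads with TGF and 0 with N, where the Control ratio would place 82.2% of the reads in the TGF libraries (two-sided exact binomial p = 1). A candidate explanation for the interaction is the floor of the log2(CPM + 1) scale, since so few AmeloD reads allow the same ratio as in Control and the estimate turned positive with edgeR (1.68) and DESeq2 (0.79). A different response of the AmeloD cells stays open, because 3 reads cannot exclude it.

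The number of genotype calls was weighed next. Of 35 splits of the 8 libraries into 4 and 4, 33 could be fitted and 2 could not. Only the real split gave as many as its 946 genes (highest other 0). A rank of 1 of 33 is the lowest this test can give. The other splits keep the genotype difference in their residual spread, so their counts do not show how many calls arise with no difference. The splits alone therefore cannot exclude a chance labelling of the libraries. The AmeloD libraries were shallower, but after thinning to the smallest library total 86.9% of the calls were made again in the same direction, which argues against depth as the cause of most of them, though the calls of Prkaca (adjusted p = 0.0636) and Tuft1 (adjusted p = 0.0892) ended at 0.50 and 0.54. The excess of higher calls may come from the deposited CPM scaling, since TMM scaling gave 52.9% higher. An effect of AmeloD cannot be told apart from any other difference between the AmeloD and Control cell populations, because the construct left 0 reads of Ascl5 and each genotype may be a single cell population.

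For TGF, only the real split gave as many as its 124 genes (1 of 33 splits, highest other 3), with the same limits. For the plasmid the real count was 0, which all 33 splits reach by construction (highest other 6), so the splits say nothing about it.

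Some of the most abundant genes were unusual for their level. Zc3h10 had a mean of 6348 CPM, B3galt4 1450 and Cd320 1224, and in RefSeq they lie beside Rpl41, Rps18 and Ndufa7. No row carries the symbols of these neighbours, and rows without a symbol were not searched for them. A candidate explanation is that reads of such neighbours were counted for Zc3h10, B3galt4 and Cd320. Prickle4, at a mean of 1596 CPM, had no such neighbour. Of 43 matched genes among the 50 most abundant, 10 (23.3%) had a neighbour without a row by its symbol, against 806 of 6071 others (13.3%). This leaves the explanation open (two-sided Fisher's exact p = 0.0686). No biological explanation was tested.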

How the results depend on the processing

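The thinned reads were chosen after the results were seen, the other alternatives before. Of 88 named results for genes, 88 kept their direction and side of the threshold with a pseudocount of 5, 88 with robust eBayes, 86 with a pseudocount of 0.5, 84 with TMM, 84 with the same median, 85 with edgeR, 80 with DESeq2 and 72 without a filter, where more genes share the adjustment. Of 59 genotype genes 47 kept their call with genotype alone, where Fn1 (adjusted p = 0.243) and Ccn2 (adjusted p = 0.138) lost it, 47 with the N libraries only (among those lost Calr 0.37, adjusted p = 0.162, and Irf7 0.48, adjusted p = 0.276) and 42 with the TGF libraries only (Hmgb2 -0.27, adjusted p = 0.401), and the genotype count was 689 with genotype alone and 749 with the N libraries. Of the 704 values with 1 library left out 618 kept both and 86 lost the call, with 0 reversed; each library ended 7 to 13 of the 86 calls. The additive fits without a library leave 3 residual degrees of freedom and the interaction fits fewer. A lone library is assumed to vary like the others. The fits with the N or TGF libraries only leave 1 residual degree of freedom. With thinned reads 82 of 87 kept their call; Prkaca and Tuft1 for genotype and Itgb6 (adjusted p = 0.0806), Col5a2 (0.0666) and Col3a1 (0.0526) for TGF lost it, with the direction kept. Robust eBayes does not enter camera, so it left the lists as they were. With TMM 855 of the 946 genotype calls were made again (90.4%).

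The genotype count was 389 and the TGF count 62 with a mean of at least 10 CPM (fewer genes tested), the TGF count 67 without a filter, and the genotype count 437 with the TGF libraries only; the cause of the last 2 was not tested. The genotype by TGF count of 1 became 0 with a pseudocount of 0.5, without a filter, with edgeR and with DESeq2, and the plasmid count 1 with DESeq2; the cause was not tested. The DNA replication and mitosis lists had adjusted p = 0.206 and 0.206 for genotype with an estimated correlation. Their unadjusted camera p rose from 9.19e-06 to 0.0605 and from 3.73e-07 to 0.0679. For the interferon list it rose from 0.519 to 0.543. With an estimated correlation camera also uses the 4 residual degrees of freedom, which enlarges small p values most at any correlation. The replication and mitosis calls were thus made in the preset setting only. How much of the loss came from correlation among their members was not tested and cannot be told from these values. Without 1 library the counts were 642 to 924 for genotype, 71 to 104 for TGF, 0 to 2 for plasmid, 0 to 7 for genotype by TGF and 0 to 2 for genotype by plasmid, with the libraries that moved a count by over 1.5 times named in the report. The Prl8a7 interaction reversed to 1.68 with edgeR and 0.79 with DESeq2.

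The set tests that reversed their direction were of lists not past the test before or after; the cause was not tested. For hypoxia and plasmid the adjusted p was 0.980 with a pseudocount of 5, 0.974 with the same median and 0.992 with TMM. Without a filter it was 0.836 for p53, 0.988 for stress and 0.854 for cholesterol genes with TGF, and with the plasmid 0.777 for Hedgehog, TGF-beta, interferon and cholesterol genes and 0.915 for mesenchymal genes. With a mean of at least 10 CPM it was 0.879 for dental and 0.142 for p53 genes with TGF. For cholesterol and genotype it was 0.970 with the same median, 0.942 with TMM and 0.813 thinned. With TMM it was 0.992 for replication and for cholesterol genes with the plasmid, and with thinned reads 0.971 for dental and for cholesterol genes with TGF. Without 1 library the adjusted p ranged, for the plasmid, over 0.317 to 0.871 for replication, 0.556 to 0.966 for cholesterol, 0.335 to 0.978 for enamel, 0.106 to 0.868 for stress, 0.640 to 0.978 for hypoxia and 0.329 to 0.984 for interferon genes. With TGF it ranged over 0.668 to 0.992 for cholesterol, 0.730 to 0.992 for dental, 0.140 to 0.992 for stress, 0.560 to 0.992 for interferon and 0.663 to 0.992 for p53 genes, and for genotype over 0.755 to 0.961 for cholesterol genes.

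Of the 8 genotype lists past camera, the dental (adjusted p = 0.0703) and FGF (adjusted p = 0.309) lists did not pass without a filter and the mesenchymal list (adjusted p = 0.173) with a mean of at least 10 CPM, while the p53 and interferon lists passed without a filter (adjusted p = 0.0296 for both). Of the 6 TGF lists, the replication (adjusted p = 0.307), epithelial (0.162) and mesenchymal (0.0683) lists did not pass without a filter, nor the epithelial list with a mean of at least 10 CPM (0.0652). The replication list did not pass without 4 of the libraries in turn (0.0837 to 0.248) and the epithelial list without 3 (0.0555 to 0.140). Few members of some lists reached the level for a test, such as 6 of 27 Hedgehog components, 5 of 20 enamel genes and 1 of 16 Wnt targets. The labels give no replicate numbers. A fit that paired the libraries, with the combinations of the other factors as a 4-level covariate, called 1035 genes for genotype, 125 for TGF and 0 for plasmid, and 87 of 87 named results for genes kept their call.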

Other observations

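The Gene Ontology tests of keratin, cell cycle and glycolysis terms and the test of shared genotype and TGF calls were written before their results were seen. They use the gene calls given above and are not independent of them. The other values in this part were chosen after their results were seen.

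Genes of keratinization were over-represented among those higher in AmeloD: 13 of the 18 tested genes of that term were called higher, where 1.65 would be expected (hypergeometric adjusted p = 1.93e-07). They include Krt5, Krt7, Krt17, Krt80, Lce1e, Lce3d, Lce3e, Sprr1a and the transglutaminase gene Tgm1, which cross-links the cornified envelope. Intermediate filament organization (9 of 16, adjusted p = 0.00170), keratinocyte differentiation (12 of 35, adjusted p = 0.0150; with Loricrin, Sprr1b and Scel) and negative regulation of cell migration (14 of 51, adjusted p = 0.0410) followed. Among genes lower in AmeloD, the glycolytic process had 7 of 19 genes where 0.922 would be expected (adjusted p = 0.0185; Eno1, Gpi, Pgk1, Pkm, Tpi1 and Enpp1 among them), and nucleosome assembly 10 of 45 (adjusted p = 0.0185), with linker histone genes such as H1f4 and H1f5. Positive regulation of smooth muscle cell migration (6 of 15, adjusted p = 0.0185) passed as well, but not with TMM scaling (adjusted p = 0.0581). DNA replication did not pass (7 of 48, adjusted p = 0.374). These values are consistent with more cornified-type expression and lower glycolytic gene expression in the AmeloD libraries, as hypotheses from the same data. Genes higher with TGF were over-represented in 12 terms, led by extracellular matrix organization (7 of 33, adjusted p = 0.00106) and integrin-mediated signalling (7 of 38, adjusted p = 0.00147). Genes lower with TGF were over-represented in 0 of 1282 terms. Only 15 of them had a term, against 97 of those higher, so the 0 says little about them.

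It was asked whether genotype and TGF move their shared genes in opposite directions. Of 52 genes called in both, 26 moved in opposite and 26 in like directions (two-sided Fisher's exact p = 1), so no excess of opposite directions was found. The counts per pairing stand beside the product of the list sizes divided by the number of genes tested. This is no value for chance here, because both calls share each gene's residual spread, and no pairing was tested. Higher in both were 19 genes (against 9.52), among them Ccn2, Fas, Krt7 and Sparc. Lower in AmeloD and higher with TGF were 20 (against 4.98), among them Fn1, Col3a1 and Igfbp5. Higher in AmeloD and lower with TGF were 6 (against 1.72), among them Ccnd1 and Krtdap. Lower in both were 7 (against 0.902), among them Anln, Mt1 and Pgk1.

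Several other genes of the prolactin family had reads in Control and 0 in AmeloD but lay below the level for a test. Prl8a3 had 96 reads (79 with TGF, 17 with N), Prl8a4 25 (19 and 6), Prl8a9 18 (16 and 2), Prl8a5 5 (3 and 2) and Prl8a2 4 (1 and 3) in Control, each with 0 in AmeloD. Reads shared among these paralogs were not separated. Genes below the level for a test were not searched for reads in a single genotype. Among tested genes, only Nts, encoding neurotensin, had at least 10 reads in each library of a genotype and 0 in the other genotype. It had 92 to 152 reads per AmeloD library, a mean of 10.4 CPM, at least 55.3-fold higher than the mean floor of 3 reads per Control library (0.189 CPM). Several TGF-beta induced genes too low for a test had more reads in the TGF than in the N libraries: Thbs1 102 and 12, Ldlrad4 64 and 32, Skil 44 and 15, Smad7 27 and 4 and Tgfb1 21 and 6, while Ccn1 had 15 and 14.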
